A study of Mus musculus with 12 samples.

How the data were processed

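Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on liver of male C57BL/6 mice aged 4 months, per the labels. The mice were either fed standard chow or fasted with water for 48 h, and the labels speak of 5 pairs of mice. How the mice map to the libraries, and whether chromatin was pooled, is not given in the sources used here. The 5 antibodies were directed against β-hydroxybutyrylated lysine (bhb) at H3K4, H3K9 and H4K8, against acetylated H3K9 (H3K9ac) and against trimethylated H3K4 (H3K4me3). β-hydroxybutyrate is the main ketone body that liver releases during fasting, and lysine β-hydroxybutyrylation is the acyl mark formed from it. H3K9ac and H3K4me3 are marks of active promoters. With an input library for each diet there were 12 libraries in 12 groups, 1 per antibody and diet, so there are no replicates. No test, p-value or standard error was therefore computed, and each difference is a difference between a pair of libraries.

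CASAVA 1.8.2, Bowtie 0.12.7 and the mm10 build were used, per the submitters' processing notes. The deposited bin files hold whole-number counts of extended reads in consecutive 200 bp bins, without normalisation by the authors. Between 99.0% and 99.3% of isolated single reads filled 2 bins, so the number of reads was taken as the total bin count divided by 2. Handling of duplicate reads is not given in the sources used here. The peak lists were made with MOSAiCS, per the file headers, 1 list per library for the 10 antibody libraries. The caller's threshold and version are not given in the sources used here. The score that the authors deposited with each peak never exceeded the mean bin count of the peak. It was used only to rank or filter peaks within a mark, since it is not scaled for depth.

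Genes and their coordinates came from a RefSeq gene table on GRCm38.p6, the assembly that mm10 names. The table holds a start and an end for each of 21887 protein-coding genes on the nuclear chromosomes, but no strand, transcript or exon. The transcript start that the plan had called for was replaced by the gene end, left or right, with more H3K4me3 summed over both diets. Exon, intron and UTR labels were not used here. A promoter window was the bin holding that gene end with 5 bins on each side, 11 bins or 2200 bp in all. Windows entered the comparison when they touched an H3K4me3 peak of either diet, and 2 windows whose input exceeded 5 times the median input were left out. This gave 12225 windows, of which 3075 share a bin with the window of another gene.

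Window counts were divided by the total bin count of the library and scaled to counts per 1000000 (CPM). The change was log2((fasted + p)/(fed + p)), where p was the median input window, 1.27 CPM. This pseudocount makes the change of weak windows smaller than their ratio. Ratios for single genes are plain ratios of CPM with an exact conditional binomial interval at the 95% level, on reads. Shares carry Wilson intervals. Reads have no molecular identifiers, so all these intervals cover counting error only. Enrichment at gene ends was the mean signal within 1 kb divided by the mean signal 8 to 10 kb away, over protein-coding genes.

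Gene lists, the rule for naming genes, the comparisons and most alternatives were fixed before the data were examined. The 26 lists hold 574 entries, of which 573 matched the gene table by symbol and 1 by synonym. They cover ketogenesis and ketone export, fatty acid oxidation and PPARalpha targets, gluconeogenesis, amino acid catabolism and the urea cycle, fatty acid synthesis, cholesterol synthesis and uptake, bile acid and xenobiotic metabolism, the insulin, IGF and FOXO axis, redox and metallothionein genes, autophagy and lysosome, the circadian clock, acute phase and interferon genes, endoplasmic reticulum stress, the cell cycle, cytosolic ribosomal proteins, oxidative phosphorylation, hepatocyte identity and housekeeping genes. Further lists hold markers of Kupffer cells, endothelium, stellate cells, cholangiocytes, lymphocytes, and granulocytes with erythroid cells, and a pair of control lists hold silent CpG-poor promoters and developmental regulators. For each list the median change minus the median of all windows was placed among 10000 random lists of the same size, matched on mean signal in 20 groups. Its percentile is a description of these libraries. Named genes were the 10 highest and 10 lowest windows in H3K9bhb and the 5 highest and 5 lowest in each other mark, with signal at least 3 times the input in the diet where the mark was higher. To these came up to 4 members of each list and 16 genes of fasting metabolism and controls fixed by name. Some of these genes are not reported here. Named peaks were, for each bhb mark, the 3 with the highest score among fasted peaks without an overlapping fed peak.

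Alternatives changed the window size, the pseudocount, the scaling, the input correction, the set of windows, the choice of gene end and the overlap rule for peaks. Overlaps were set beside the same overlaps with 1 list shifted along the genome. The fold and list steps were tested on simulated data drawn from the mean of the H3K9bhb libraries. Of 100 windows with a true 4-fold difference 99 passed the 2-fold threshold, and of 100 with a true 2-fold difference 21 did, since the pseudocount brought their median to 0.85. Of 12026 unchanged windows 0 passed in either direction. Of 100 unchanged lists of 25 windows 3 lay outside the central 95%, and of 100 lists raised by 0.3 log2 all 100 did. The simulation held counting error only, without a shift of all windows, and its lists were drawn at random. The real H3K9bhb pair had a median shift of 0.64 log2 and its lists were chosen by function. These counts therefore check the calculation and do not give error rates for the real libraries. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.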

Results

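The series profiled histone lysine β-hydroxybutyrylation in liver of fed mice and of mice fasted for 48 h, with 1 library for each antibody and diet. It asks where these marks lie and how their levels differ when ketone bodies are high. The fed libraries held 14.8 M reads (M, mega) for H3K4bhb, 11.5 M for H3K9bhb, 17.0 M for H4K8bhb, 23.9 M for H3K9ac, 28.8 M for H3K4me3 and 29.9 M for input. The fasted libraries held 12.98, 19.98, 12.6, 18.9, 20.3 and 25.3 M in the same order. Only H3K9bhb was deeper in fasted liver, and its fed windows, with a median of 47.5 reads, are the less precise of the pair.

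All 3 bhb marks stood higher over gene ends in fasted than in fed liver, and so did H3K4me3, a mark of active promoters, while H3K9ac stood slightly lower. H3K9bhb signal within 1 kb of gene ends was 2.03 times that of the flanks in the fed library and 3.19 times in the fasted library, a ratio of 1.57. The corresponding values were 1.51 and 2.20 for H3K4bhb, 1.42 and 2.14 for H4K8bhb, 7.72 and 13.3 for H3K4me3 and 8.11 and 7.53 for H3K9ac. Input gave 1.11 in both diets. In the 12225 promoter windows the median H3K9bhb level was 4.12 CPM in fed and 7.13 CPM in fasted liver, against 1.52 and 1.44 CPM in input.

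**Figure D1:**
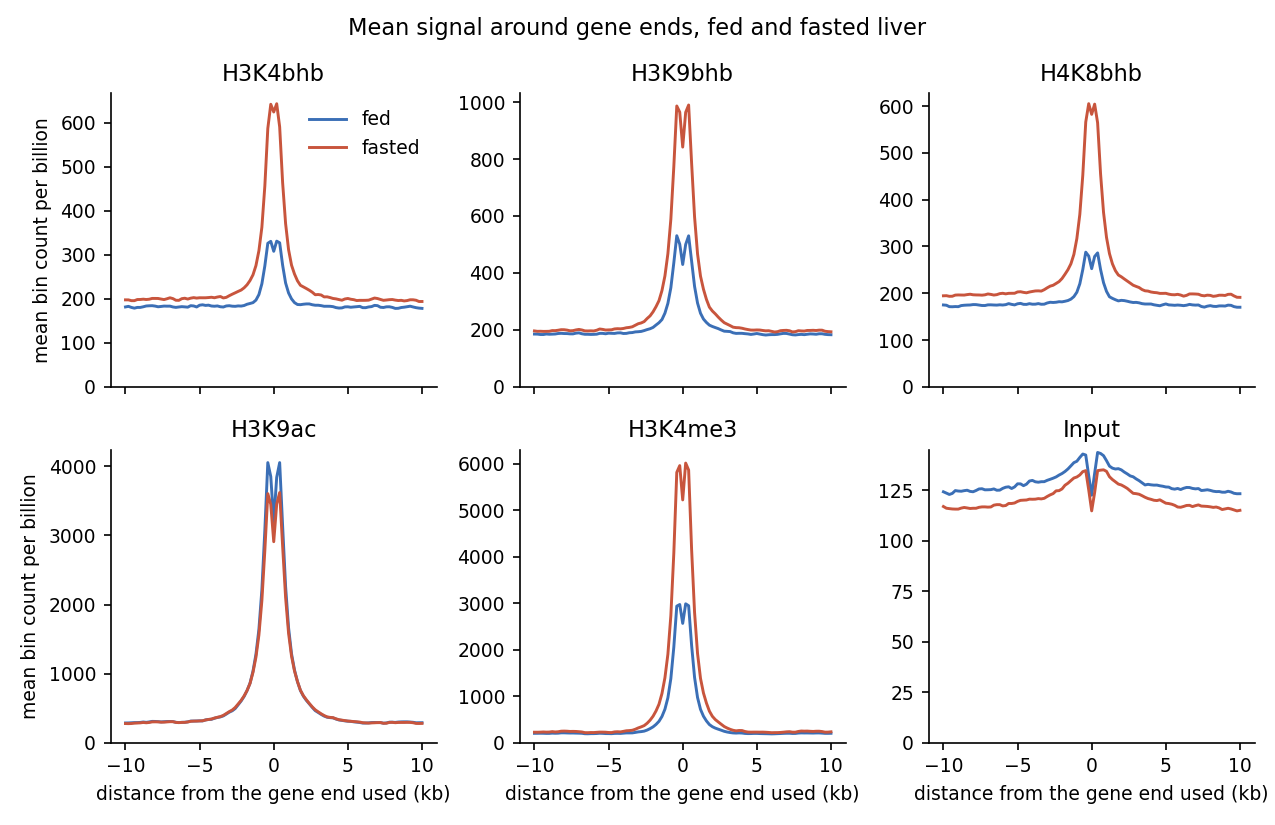
Mean bin count scaled to the library total (vertical axis, starting at 0) against distance in kb from the gene end used, for 5 marks and input in windows with an H3K4me3 peak, with fed in blue and fasted in red and 1 library per line. The fasted line lies above the fed line at the gene end in the 3 bhb marks and H3K4me3, where enrichment ratios in these windows were 1.604 to 1.73, and below it in H3K9ac, where the ratio was 0.931.

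Across promoter windows the median log2 difference between fasted and fed liver was 0.60 for H3K4bhb, 0.64 for H3K9bhb, 0.67 for H4K8bhb, 0.88 for H3K4me3 and -0.10 for H3K9ac, with -0.04 for input. The fasted library was higher in 94.2% of windows for H3K9bhb and in 33.6% for H3K9ac. At least 2-fold higher in fasted liver were 1159 windows for H3K4bhb, 1803 for H3K9bhb, 1903 for H4K8bhb, 4185 for H3K4me3 and 21 for H3K9ac, and at least 2-fold lower were 0, 0, 0, 6 and 82. With each mark centred on its median window, these splits became 3 higher against 52 lower, 11 against 67, 5 against 65, 35 against 698 and 25 against 46. List medians, and log2 values of single genes where so stated, are therefore given below relative to the median window. The CPM and ratios of single genes are not centred and include the shift of the median window. Scaling to the signal outside peaks set the medians to 0.68, 0.75, 0.76, 1.95 and -0.34, and 17 windows higher against 334 lower in H3K9ac. Input had 0 windows past 2-fold in either direction.

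**Figure D2:**
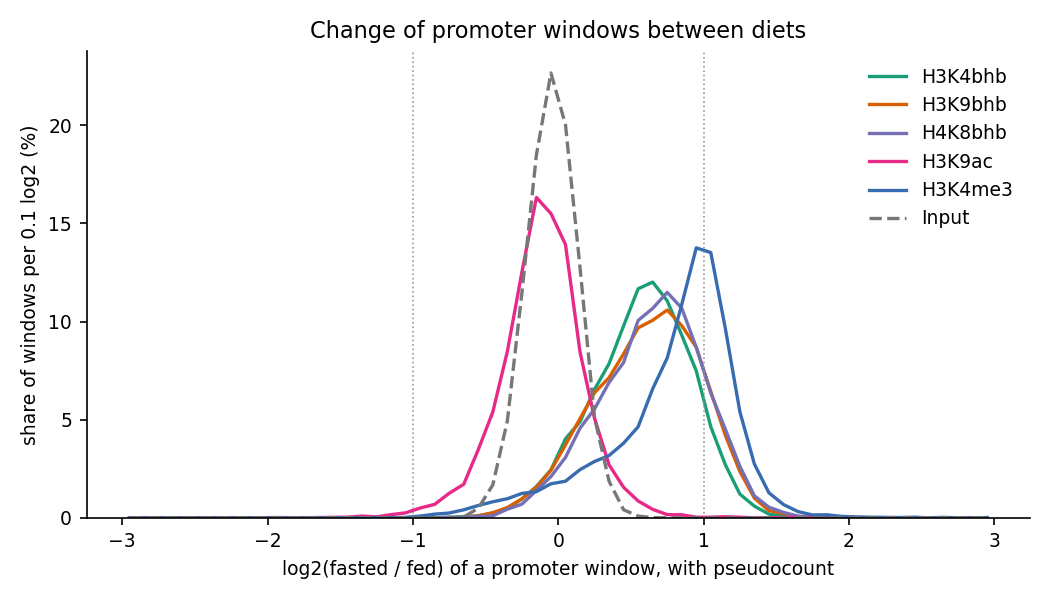
Share of the 12225 promoter windows (percent per 0.1 log2) against their log2 ratio of fasted to fed signal, for 5 marks (solid) and input (dashed), with dotted lines at a 2-fold difference. The bhb marks peak between the input, whose median was -0.04, and H3K4me3, whose median was 0.88.

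By the log2 difference with pseudocount, H3K9bhb was highest relative to fed liver at Cebpd, the gene of the transcription factor C/EBPδ (chromosome 16, 15887286 to 15889545, GRCm38), which held 6.42 CPM in fed and 32.7 CPM in fasted liver, a ratio of 5.08 (95% interval 3.99 to 6.55). Its window overlaps that of Spidr, with 2.47 and 11.4 CPM. Agxt, a peroxisomal aminotransferase that takes part in glyoxylate and alanine metabolism (chromosome 1, 93135240 to 93145421), held 6.90 and 25.5 CPM, a ratio of 3.71 (2.92 to 4.76). Gadd45g, a stress-inducible gene (chromosome 13, 51846675 to 51848475), held 9.12 and 32.4 CPM. Eif4ebp3, which encodes a repressor of cap-dependent translation, held 2.00 and 9.46 CPM, and Fbxo31, an F-box protein gene, 8.07 and 28.5 CPM. The others among the 10 highest were Sbf2 with a ratio of 5.77, Smarcad1, a chromatin remodeller, with 5.45, Txndc15 with 4.50 and Caprin1, which encodes an RNA-binding protein, with 3.85. At Sbf2 and Smarcad1 the fed windows were weak, at 1.39 and 1.56 CPM.

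In fasted liver the 10 lowest H3K9bhb windows held no more than 3.40 CPM. Tubb2b, a neuronal tubulin gene, held 5.34 CPM in fed and 3.30 CPM in fasted liver, a ratio of 0.624 (0.434 to 0.899). The ratio was 0.577 at Srpk3, 0.609 at Fstl3, 0.667 at AI467606, 0.654 at Baiap3, 0.676 at Nmrk2 and 0.603 at Arl14. At Zdbf2, Spag6l and Sh3gl2 it was 0.490, 0.507 and 0.577, from at most 2.21 CPM in either diet. Not one of these 10 genes belongs to a fixed list.

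Several genes of fasting metabolism that were fixed by name lay near the median window in H3K9bhb. Bdh1, which makes β-hydroxybutyrate from acetoacetate, held 2.60 CPM in fed and 3.65 CPM in fasted liver, -0.29 log2 relative to the median window. Cpt1a, which admits fatty acids to mitochondria, held 6.55 and 10.99 CPM at 0.01, Pck1, of gluconeogenesis, 7.73 and 12.3 CPM at -0.05, and Fgf21, a fasting hormone, 6.60 and 10.9 CPM at -0.01. G6pc was at 0.31, Igfbp1 at 0.28, Pdk4 at 0.07, Fasn at 0.15, Scd1 at -0.36 and Actb at 0.16. All of these lay within counting error of the median window. Angptl4, an inhibitor of lipoprotein lipase (chromosome 17, 33774900 to 33781575), stood apart with 8.38 and 25.8 CPM, a ratio of 3.10 (2.49 to 3.90) and 0.85 log2 above the median window. Ppargc1a gave 2.56 and 2.85 CPM at the gene end used, Srebf1 had no H3K4me3 peak at its end, and Alb held under 0.2 CPM in both libraries.

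**Figure D3:**
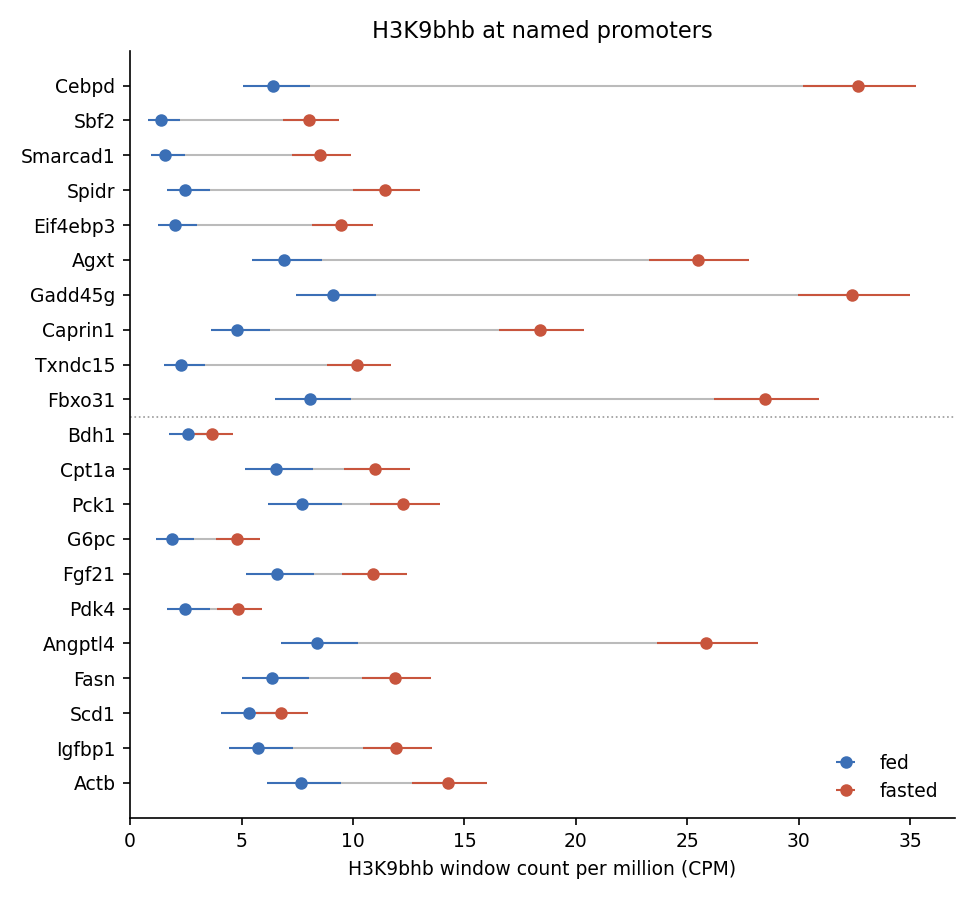
H3K9bhb window signal in CPM (horizontal axis) of the 10 highest genes (above the dotted line) and of genes fixed by name, fed in blue and fasted in red, with 95% exact Poisson bars that cover counting error only. Cebpd stands at 6.42 and 32.7 CPM and Angptl4 at 8.38 and 25.8 CPM, while Bdh1 and Scd1 have overlapping bars.

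Genes of amino acid catabolism and the urea cycle, through which fasting liver disposes of amino nitrogen, had larger fasted to fed ratios than other promoters in H3K9bhb, H3K9ac and H3K4me3. Of 44 measured members 34 lay above the median window in H3K9bhb, 13 of them by more than counting error, and the list median was 0.30 (percentile 100). In H3K9ac it was 0.26 and in H3K4me3 0.37, both at percentile 100. Beside Agxt, H3K9bhb held 4.90 and 12.9 CPM at Fah, of tyrosine breakdown, and 6.03 and 15.4 CPM at Slc25a15, the mitochondrial ornithine carrier. In H3K4bhb the median was 0.08 (percentile 97.8), outside random lists in 4 of 10 alternatives, and in H4K8bhb it was 0.07, within the central 95% of random lists.

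Genes of fatty acid oxidation and PPARα targets had an H3K9bhb median of 0.17 (percentile 99.0), with 28 of 38 members above the median window and 3 beyond counting error. Acadm, a medium-chain acyl-CoA dehydrogenase, held 2.86 and 9.24 CPM and Ech1, of β-oxidation, 6.38 and 17.1 CPM. Acaa1b, a peroxisomal thiolase, went the other way with 8.68 and 8.16 CPM. The list was above random lists at 0.21 in H3K4me3, in all 10 alternatives, and at 0.10 in H3K4bhb, in 7 of 10, and was at 0.09 in H4K8bhb and 0.04 in H3K9ac, within them. Its H3K9bhb result held in 4 of 10 alternatives, and with windows of 500 bp or 2 kb on each side the median lay within the central 95% of random lists. The 7 genes of ketogenesis and ketone export were within it in H3K9bhb, at 0.15, with Acat1 at 2.13 and 8.96 CPM, and above it in H3K4me3, at 0.28, which held in 3 of 10 alternatives. Gluconeogenesis was within it in each mark, at 0.21 in H3K9bhb, where Foxo1 held 7.99 and 23.2 CPM.

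Promoters of cytosolic ribosomal proteins and of oxidative phosphorylation, sets of genes active in nearly all cells, had the highest list medians in H3K9bhb, 0.45 and 0.46 (both percentile 99.99). The ribosomal result held in 9 of 10 alternatives and was lost with windows of 500 bp on each side. Of 29 ribosomal protein genes 28 lay above the median window, with Rpl27 at 3.73 and 14.1 CPM and Rps23 at 3.13 and 11.7 CPM. Of 27 genes of oxidative phosphorylation 24 did, with Ndufa4 at 2.60 and 8.86 CPM and Atp5c1 at 8.07 and 23.8 CPM, in windows that overlap those of Phf14 and Kin. Both lists were also above random lists in H3K9ac, at 0.19 and 0.18, and in H3K4me3, at 0.37 and 0.27, and the ribosomal list in H3K4bhb, at 0.24, which held in 4 of 10 alternatives. The housekeeping list was within them in each mark, at 0.17 in H3K9bhb.

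Lipid synthesis promoters had smaller fasted to fed ratios than the median window in H3K9bhb, H3K9ac and H3K4me3. Genes of cholesterol synthesis and uptake had a median of -0.33 in H3K9bhb, -0.83 in H3K9ac and -0.50 in H3K4me3, each at percentile 0, and -0.032 in H3K9bhb and 0.15 in H3K4me3 when set against all protein-coding windows. In H3K9bhb 18 of 23 members lay below the median window. Mvd and Fdps, of the mevalonate pathway, held 13.9 and 11.6 CPM and 8.64 and 7.68 CPM of H3K9bhb in fed and fasted liver, and 111 and 40.7 CPM and 72.0 and 24.9 CPM of H3K9ac, and Stard4, a sterol carrier gene, 6.21 and 5.33 CPM. The same list had medians of 0.11 in H3K4bhb and 0.19 in H4K8bhb, within random lists. Fatty acid synthesis was at -0.14 in H3K9bhb, -0.61 in H3K9ac and -0.42 in H3K4me3, with 16 of 22 members below the median window in H3K9bhb. In H3K9bhb 3 members were lower and 2 higher by more than counting error, and the interval of the median over genes, -0.23 to 0.054, held 0. Acly, which makes cytosolic acetyl-CoA, held 19.3 and 19.5 CPM of H3K9bhb, and Mlxipl, which encodes the glucose-responsive factor ChREBP, 8.77 and 9.79 CPM. Acacb went the other way, with 8.12 and 20.1 CPM. Taking the median bin of a window in place of the sum set the H3K9bhb value of fatty acid synthesis to 0.11, and taking all protein-coding windows set it to 0.24.

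**Figure D4:**
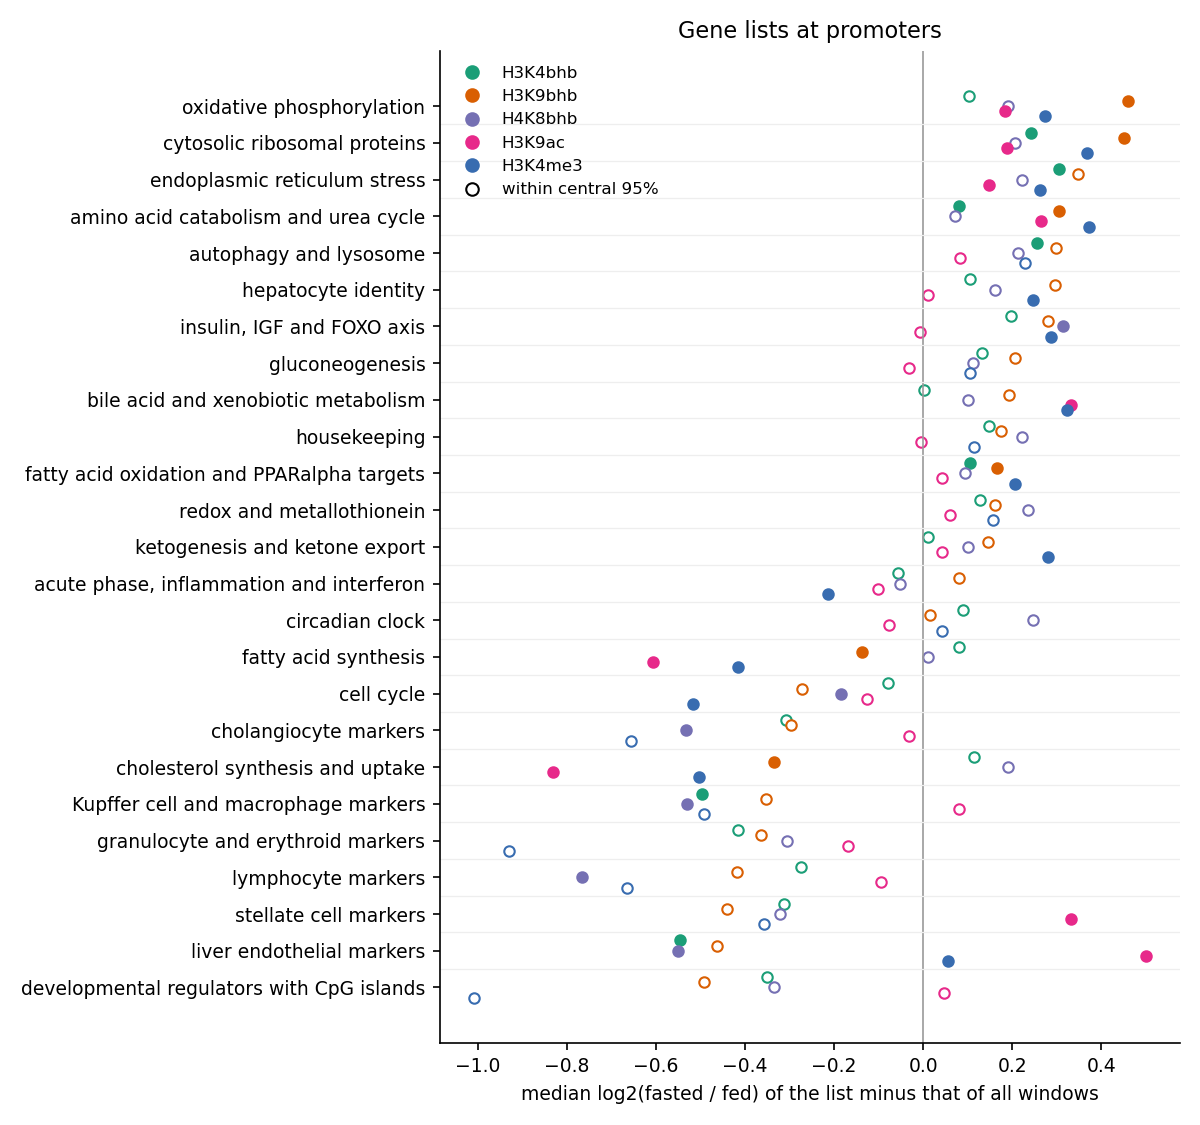
Median log2 difference of each gene list minus that of all windows (horizontal axis) for 25 lists and 5 marks, coloured by mark, with filled circles where the median lies outside the central 95% of 10000 matched random lists. Cholesterol synthesis lies at -0.33 in H3K9bhb and -0.83 in H3K9ac, and oxidative phosphorylation at 0.46 in H3K9bhb.

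Endoplasmic reticulum stress genes had a median of 0.30 in H3K4bhb, 0.15 in H3K9ac and 0.26 in H3K4me3, above random lists, and 0.35 in H3K9bhb, within them, with Calr, a chaperone of that compartment, at 12.5 and 33.2 CPM of H3K9bhb. Their H3K9ac result held in 9 of 10 alternatives, with a median of -0.0044 by the median bin, and their H3K4me3 result in 9 of 10. Autophagy and lysosome genes were at 0.25 in H3K4bhb, above random lists, with Bnip3 at 1.96 and 5.66 CPM, and at 0.30 in H3K9bhb, within them. Against random lists matched on H3K4me3 signal, all 5 lists above random lists in H3K4bhb lay within them, these stress and autophagy lists included. The insulin, IGF and FOXO axis was at 0.31 in H4K8bhb and 0.29 in H3K4me3, above random lists, and at 0.28 in H3K9bhb, where Ddit4, an inhibitor of mTORC1, held 10.5 and 34.4 CPM and Gadd45b 10.1 and 30.7 CPM. Redox and metallothionein genes, the circadian clock and acute phase genes were within random lists in H3K9bhb, at 0.16, 0.02 and 0.08, the redox list was above them in input, at 0.11, and acute phase genes were below them in H3K4me3, at -0.21, which held in 6 of 10 alternatives. In the clock list Per1 held 11.6 and 34.5 CPM of H3K9bhb, though its log2 difference reversed to -0.065 with the median bin of the window. Cell cycle genes were below random lists at -0.52 in H3K4me3, in all 10 alternatives, and at -0.19 in H4K8bhb, in 5 of 10, though with all protein-coding windows the medians were 0.13 and 0.16, and were at -0.27 in H3K9bhb, within them. Of the 25 lists with a value, 4 were above and 2 below random lists in H3K9bhb, 5 and 2 in H3K4bhb, 1 and 5 in H4K8bhb, 7 and 2 in H3K9ac, 10 and 4 in H3K4me3, and 2 and 0 in input.

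Hepatocyte identity genes lay at 0.29 in H3K9bhb, within random lists, and at 0.25 in H3K4me3, above them in 6 of 10 alternatives too, with Apoe at 9.68 and 25.3 CPM of H3K9bhb. Bile acid and xenobiotic genes were at 0.33 in H3K9ac and 0.32 in H3K4me3, above random lists, and at 0.19 in H3K9bhb, and the same list was at 0.09 in input, also above them. Some markers of other liver cells had smaller fasted to fed ratios of H3K4bhb or H4K8bhb than random lists. Liver endothelial markers were at -0.55 in H3K4bhb and -0.55 in H4K8bhb, below random lists, which held in 8 and 6 of 10 alternatives, and at 0.50 in H3K9ac and 0.06 in H3K4me3, above them. Stab1, a scavenger receptor of liver sinusoids (chromosome 14, 31139017 to 31168651), held 6.59 and 4.32 CPM of H3K4bhb, and 14.1 and 19.3 CPM of H3K9ac. Kupffer cell markers were at -0.50 in H3K4bhb and -0.53 in H4K8bhb, cholangiocyte markers at -0.53 and lymphocyte markers, with 3 measured genes, at -0.77 in H4K8bhb, all below random lists. Against lists matched on H3K4me3 signal the Kupffer cell and cholangiocyte values lay within them. Stellate cell markers were at 0.33 in H3K9ac, above them. In H3K9bhb the medians were -0.46 for endothelial, -0.35 for Kupffer cell, -0.44 for stellate, -0.30 for cholangiocyte, -0.42 for lymphocyte and -0.37 for granulocyte and erythroid markers, and -0.49 for developmental regulators, all within random lists. None of the 23 silent control promoters had an H3K4me3 peak, so that list has no value.

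The 5 highest genes of H3K4bhb and of H4K8bhb were not among the 10 highest of H3K9bhb. They are extremes of 12225 windows whose fed medians were 42.5 reads in H3K4bhb and 44.0 in H4K8bhb. This does not show that the marks favour different genes, and the intervals do not allow for the selection. The highest H3K4bhb windows were Kyat3, a kynurenine aminotransferase gene, with 1.28 CPM in fed and 6.94 CPM in fasted liver (ratio 5.40, 3.27 to 9.39), Nck1 with 2.23 and 9.59 CPM, Tpra1 with 4.09 and 15.0 CPM, Hnrnpr with 2.57 and 10.3 CPM and Tomm40 with 1.79 and 7.59 CPM. In H4K8bhb they were Dbp, a clock output gene, with 2.14 and 11.1 CPM (ratio 5.24, 3.61 to 7.78), Hspa9, a mitochondrial chaperone gene, with 3.46 and 14.5 CPM, Ctdsp1 with 2.43 and 11.02 CPM, Cstf2t with 1.50 and 7.72 CPM and Ctcf, the insulator protein gene, with 1.53 and 7.72 CPM. At Kyat3, Tomm40, Cstf2t and Ctcf the fed windows were weak, at 1.28 to 1.79 CPM, near the fed input median of 1.52 CPM. Dbp, whose window overlaps that of Car11, had 141 CPM of H3K9ac in fed and 108 CPM in fasted liver. The lowest windows were Scrg1, Efcab8, Dnah10, Meioc and Lrrc10 in H3K4bhb and Cmtm1, Bmp3, Gpx6, Olfr315 and Egflam in H4K8bhb, with no more than 4.90 CPM in either diet.

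In H3K9ac the windows furthest below the median included Igfbp5 with 22.5 and 4.72 CPM, Sqle, of sterol synthesis, with 67.9 and 16.5 CPM, Rnf186 with 116 and 31.3 CPM and Ihh with 31.0 and 8.22 CPM. The highest were Nlrp12 with 4.15 and 17.2 CPM, Cyp2b10, a xenobiotic-inducible cytochrome, with 5.91 and 23.1 CPM, Defb1 with 0.314 and 3.61 CPM, Cyp4a14, a PPARα target, with 3.66 and 12.96 CPM, and Spidr. The highest H3K4me3 windows were Eif4ebp3 with 6.09 and 58.1 CPM, Insig2, a regulator of sterol synthesis, with 4.48 and 41.8 CPM, Orm3 with 5.31 and 41.0 CPM, Gadd45b with 24.6 and 160 CPM, and Spidr. The lowest included Rnf186 with 75.5 and 28.6 CPM, Igfbp5, Ccer1 and Serpina6.

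Among fasted bhb peaks that overlap no fed peak of the same mark, those with the 3 highest scores of the authors lay mostly within genes. For H3K9bhb they were chromosome 14, 70350801 to 70351000, within Slc39a14, a zinc transporter gene, chromosome 5, 23434801 to 23435200, within Kmt2e, and chromosome 10, 77112801 to 77113800, within Col18a1, with mean bin counts of 298, 342 and 307 in fasted and 86.0, 73.5 and 83.6 in fed liver, where the fasted library held 1.73 times the reads. For H3K4bhb they were chromosome 2, 130423801 to 130424000, within Pced1a, chromosome 2, 52742401 to 52742600, 252 bp from Stam2, and chromosome 5, 121837201 to 121837600, within Sh2b3. Their mean bin counts were 60, 60 and 56 in fasted and 16, 15 and 19.5 in fed liver. The input there held 6, 4 and 4.5 in fasted and 5, 13 and 13 in fed liver. For H4K8bhb the peaks were chromosome 10, 59970601 to 59970800, which lies 16609 bp from Anapc16, chromosome 5, 130032601 to 130032800, within Crcp, and chromosome 6, 113377801 to 113378000, within Tada3. Their mean bin counts were 62, 56 and 53 in fasted liver. In fed liver the first and second held 29 and 25, and the peak within Tada3 held less. The input there held 5, 4 and 4 in fasted and 14, 18 and 14 in fed liver. These counts are not scaled for depth. Fed bins at all the named peaks held counts of the mark, so a missing fed call does not show that the mark was absent.

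The authors' lists held more bhb peaks in fasted liver. H3K4bhb had 2406 fed and 20577 fasted peaks, H3K9bhb 1097 and 15416, and H4K8bhb 813 and 4692, covering 0.517 and 4.98 Mb, 0.238 and 4.36 Mb, and 0.169 and 1.06 Mb. H3K9ac had 48127 and 56820 peaks over 34.7 and 40.9 Mb, and H3K4me3 25467 and 20206 over 11.1 and 20.4 Mb. Of fasted H3K9bhb peaks 37.7% (Wilson interval 36.9 to 38.5) lay within 1 kb of a gene end, 43.3% elsewhere in a gene and 19.0% between genes, where the genome has 3.18%, 36.2% and 60.7%. The share at gene ends was 23.2% in fasted H3K4bhb and 34.5% in fasted H4K8bhb peaks, and 57.1% in fasted H3K4me3 peaks. Fasted H3K9bhb peaks overlapped a fasted H3K9ac peak in 61.6% of cases and a fasted H3K4me3 peak in 53.1%, and fed peaks a fed H3K9ac peak in 55.6% and a fed H3K4me3 peak in 86.9%. Lists of the same diet share an input, so part of this overlap can come from peak calling.

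Few fasted bhb peaks overlapped a fed peak of the same mark by 1 bp or more. The share was 1.38% (1.20 to 1.57) in H3K9bhb, 0.428% in H3K4bhb and 0.107% in H4K8bhb, against 49.7% in H3K9ac and 54.1% in H3K4me3. Fasted H3K9bhb peaks without a fed peak held 0.601 CPM per bin in the fasted and 0.434 CPM in the fed library, and had a median count of 1 in the fasted input but 8 in the fed input. Among the strongest bins, taken in equal numbers from each diet, 61.0% of H3K9bhb bins were shared between diets, 18.6% in H3K4bhb, 8.68% in H4K8bhb, 86.7% in H3K9ac and 85.2% in H3K4me3, with at most 2.10% after shifting. In peaks of either diet lay 1.55% of fed and 2.80% of fasted H3K9bhb signal, 1.33% and 1.94% for H3K4bhb, 0.377% and 0.498% for H4K8bhb, 68.3% and 62.9% for H3K9ac and 32.4% and 64.7% for H3K4me3. For the bhb marks the fasted lists made up most of this combined length. They covered 4.36 of 4.55 Mb in H3K9bhb, 4.98 of 5.48 Mb in H3K4bhb and 1.06 of 1.23 Mb in H4K8bhb. Those bins were called on the fasted library, so a higher fasted share of bhb signal there is favoured by the choice of bins.

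**Figure D5:**
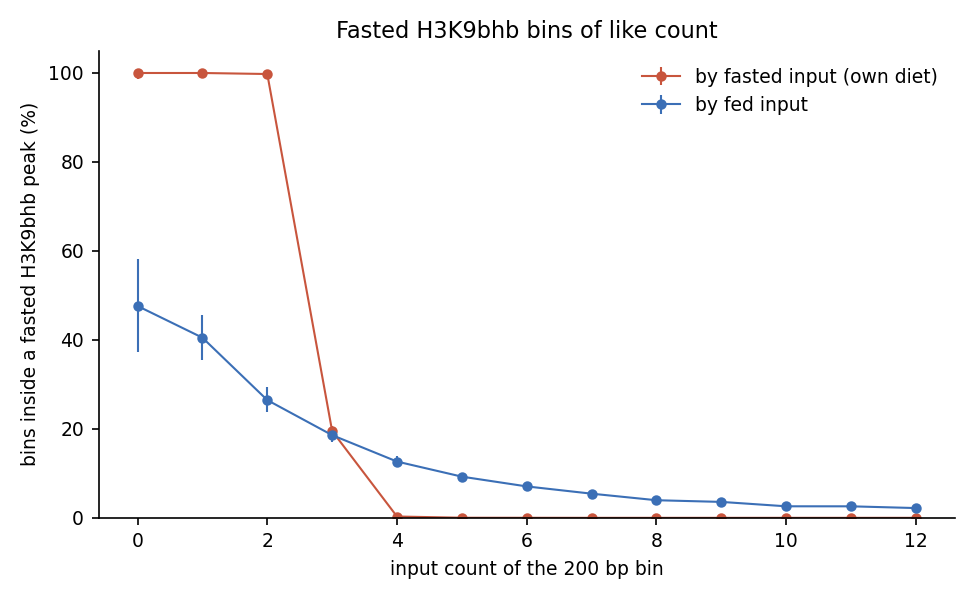
Share of 200 bp bins with 24 to 47 fasted H3K9bhb counts that lie in a fasted H3K9bhb peak (percent, with 95% Wilson bars) against the count of the bin in the fasted input (red) or in the fed input (blue). By the fasted input 99.8% of bins with a count of 2 or fewer lay in a peak, and by the fed input 31.6%.

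Differences between diets were related across promoters, for H3K9bhb most closely with H3K4me3. Spearman's correlation across the 12225 windows was 0.71 for that pair, 0.55 to 0.59 for pairs of bhb marks, 0.45 for H3K9ac with H3K4me3, and 0.19 for H3K9bhb with H3K9ac. With all protein-coding windows the last 2 pairs were at -0.055 and -0.14, and the median bin put the last at -0.032. In the main set it was -0.02 for H3K9ac with H3K4bhb and 0.00 with H4K8bhb, and reached 0.10 for input with any mark. In the bhb marks and H3K4me3, windows with more H3K4me3 differed more between diets, and relative to windows of like H3K4me3 signal it was 0.39 for H3K9bhb with H3K4me3, 0.32 for H3K9bhb with H3K9ac, and 0.17 to 0.26 for pairs of bhb marks. Genes are not independent replicates, so no p-value is given for the 15 pairs.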

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

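Liver endothelial markers stood apart in the plan's comparison of lists between marks. Their median relative to all windows was -0.55 in H3K4bhb and 0.06 in H3K4me3, and the first minus the second was -0.60. With 1 library per group this difference was not tested, and the H3K4me3 value turned negative with 3 other settings.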

How the results depend on the processing

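With 1 library per group, animals, chromatin preparation and diet cannot be separated in any value here. Some settings were chosen after seeing the data. These use extended peaks, strongest bins, unshared windows, the median bin, the highest H3K4me3 bin or windows of like H3K4me3 signal. The gene end with the most H3K9ac, thinning of the deeper library and random lists matched on H3K4me3 signal were also chosen then. The rest were chosen before. The most upstream annotated transcript start was not run, since the gene table gives no strand. The cause of each shift was not tested unless stated. Of 42 lists outside the central 95% of random lists, counted over the 5 marks, 17 stayed outside it in all 10 alternatives. These were amino acid catabolism and cholesterol synthesis in H3K9bhb, H3K9ac and H3K4me3, fatty acid synthesis, ribosomal proteins and bile acid metabolism in H3K9ac and H3K4me3, oxidative phosphorylation in H3K9bhb and H3K9ac, fatty acid oxidation and the cell cycle in H3K4me3, and endothelial markers in H3K9ac. Random lists matched on H3K4me3 signal, also chosen after seeing the data, took all 5 high lists of H3K4bhb, Kupffer cell markers in H3K4bhb and H4K8bhb, and cholangiocyte markers and the cell cycle in H4K8bhb into the central 95%.

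Peak overlap between diets, as the percent of fasted peaks overlapping a fed peak, moved with the rule. Above the median score it was 0.285 in H3K4bhb, 76.9 in H3K9ac and 76.1 in H3K4me3, and the ratio of peak numbers in H3K9bhb was 32.7. After extending peaks by 1 kb the percentages were 1.21 in H3K4bhb, 2.88 in H3K9bhb, 0.298 in H4K8bhb, 72.9 in H3K9ac and 62.97 in H3K4me3. Reciprocal overlap of 50% gave 0.642 in H3K9bhb, 33.5 in H3K9ac and 29.1 in H3K4me3. Another measure ranks bins by count and does not compare peaks. The percent of the strongest bins, in equal numbers per diet, that both diets shared was 18.6 in H3K4bhb, 61.0 in H3K9bhb and 8.68 in H4K8bhb. It was 86.7 in H3K9ac and 85.2 in H3K4me3. With H3K4me3 peaks for every mark the ratio of signal in peaks was 1.68 in H3K4bhb, 1.78 in H3K9bhb, 1.84 in H4K8bhb and 0.905 in H3K9ac. In windows with an H3K4me3 peak the ratio of enrichment at gene ends was 1.604 in H3K4bhb and 1.69 in H4K8bhb.

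The number of windows past 2-fold moved with most settings, and in the bhb marks it was highest with input subtracted. With 500 bp on each side 2997 windows were higher in H3K4bhb, 3084 in H3K9bhb and 4128 in H4K8bhb, and 1, 1 and 14 were lower in H3K4bhb, H4K8bhb and H3K4me3. With 2 kb the higher counts were 181, 663 and 406, and 1 window was lower in H3K9bhb. A pseudocount 4 times smaller gave 3080 higher and 7 lower in H3K4bhb, 3231 and 3 in H3K9bhb, 4214 and 11 in H4K8bhb, 37 and 144 in H3K9ac, and 112 lower in H3K4me3. Multiplied by 4 it gave 6 higher in H3K4bhb, 152 in H3K9bhb, 11 in H4K8bhb, 8 higher and 36 lower in H3K9ac, and 2484 and 2 in H3K4me3. Scaling outside peaks gave 1994, 3104 and 2962 higher in the bhb marks, 334 lower in H3K9ac, and 11129 higher and 1 lower in H3K4me3. Centring gave 3 and 52, 11 and 67, 5 and 65, and 35 and 698 in the bhb marks and H3K4me3, and 46 lower in H3K9ac. Subtracting input gave 4695 and 9, 4428 and 2, 5910 and 4, and 47 and 139 in the bhb marks and H3K9ac, and 48 lower in H3K4me3. Windows with a peak of the mark itself numbered 477 higher in H3K4bhb and 396 in H4K8bhb. Unshared windows gave 739, 1158 and 1218 higher in the bhb marks and 2 lower in H3K4me3. The median bin gave 1843 and 13 in H3K4bhb, 5, 12 and 47 lower in H3K9bhb, H4K8bhb and H3K4me3, and 198 higher in H3K9ac. All protein-coding windows gave 1, 1 and 1 lower in the bhb marks and 56 in H3K4me3, and the highest H3K4me3 bin 10 lower in H3K4me3.

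With all protein-coding windows, silent windows lower the median that the lists are set against. There the H3K9bhb medians were 0.52 for fatty acid oxidation, 0.68 for amino acid catabolism, 0.83 for ribosomal proteins, 0.82 for oxidative phosphorylation and -0.032 for cholesterol synthesis. Signs reversed for fatty acid synthesis, 0.24 in H3K9bhb and 0.19 in H3K4me3, cholesterol synthesis in H3K4me3, 0.15, and the cell cycle, 0.16 in H4K8bhb and 0.13 in H3K4me3. The correlation was 0.72 for H3K4bhb with H3K9bhb and 0.75 for H3K9bhb with H4K8bhb, and reversed to -0.14 for H3K9bhb with H3K9ac, -0.038 for H3K9bhb with input and -0.055 for H3K9ac with H3K4me3. With the median bin, signs reversed for amino acid catabolism in H3K4bhb, -0.058, fatty acid synthesis in H3K9bhb, 0.11, acute phase genes in H3K4me3, 0.074, endoplasmic reticulum stress in H3K9ac, -0.0044, endothelial markers in H3K4me3, -0.14, and Per1 in H3K9bhb, -0.065, and ribosomal proteins were at 0.34 in H3K9bhb. The correlation was then 0.39 for H3K4bhb with H3K9bhb, 0.44 for H3K9bhb with H4K8bhb, 0.51 for H3K9bhb with H3K4me3, and reversed to -0.032 for H3K9bhb with H3K9ac. In windows of like H3K4me3 signal it was 0.17, 0.19 and 0.39 for the first 3 of these pairs, 0.32 for H3K9bhb with H3K9ac, and reversed to 0.013 for H3K4bhb with H3K9ac. The smaller pseudocount also reversed that last pair, to 0.024, and subtracting input reversed H3K9bhb with input to -0.14 and H3K9ac with input to -0.0070. Endothelial markers in H3K4me3 reversed to -0.037 with 500 bp windows and -0.21 with the larger pseudocount. Ribosomal proteins were at 0.31 in H3K9bhb with 500 bp windows, no longer above random lists.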

Other observations

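All tests in this part were chosen after the results had been seen. Promoters with less H3K9ac, an acetyl mark of active genes, in fasted liver also had smaller fasted to fed ratios of H3K9bhb and H3K4me3 than the median window. The 82 windows at least 2-fold lower in H3K9ac, Sqle and Igfbp5 among them, had a median H3K9bhb difference of -0.45 relative to all windows, and 82 of 82 lay below the median window. Random lists matched on signal ranged from -0.09 to 0.08. The H3K4me3 median of these windows was -0.9975. It was -0.07 in H3K4bhb, -0.10 in H4K8bhb and -0.08 in input, and each of these, input included, also lay below its random lists, at percentiles 0.32, 0.03 and 0.03. The 21 windows at least 2-fold higher in H3K9ac, with Cyp2b10 and Cyp4a14, had a median of 0.65 in H3K4me3. That value lay above its random lists, at percentile 100. Their median was -0.34 in H3K4bhb, below its random lists at percentile 1.995. The medians of -0.01 in H3K9bhb, at percentile 97.2, and -0.14 in H4K8bhb both lay within their random lists.

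Higher promoter signal in the fasted libraries of the bhb marks and H3K4me3 could come from the chromatin or from the libraries. Greater depth of the fasted library was excluded for H3K4bhb, H4K8bhb and H3K4me3. Their fasted libraries had fewer reads, and the lowest median among these 3 marks was 0.60. The fasted H3K9bhb library held 1.73 times the reads of the fed library, so this test does not cover it. Enrichment that differed between libraries and more bhb on promoters of fasted liver cannot be told apart here. H3K4me3, which is not made from ketone bodies, had the largest ratio of enrichment at gene ends, 1.72, H3K9ac had 0.928, and the lowest bhb ratio was 1.45. Spike-in chromatin or replicate livers would separate them.

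Fed and fasted peak lists of the bhb marks share few peaks, which may reflect the caller's use of the input. In the fasted lists, bins of like mark count lay in a peak more often where the input of the same diet was low, by at least 83.9 points. For the fed lists the difference was 44.8 points in H3K4bhb, 60.6 in H3K9bhb and 10.7 in H4K8bhb, so 2 of 3 lists fell short of the 50 points set for each. In all 3, 100% of bins with an input count of 0 and 0% of those with 6 or more lay in a peak. In fed H4K8bhb the share was 28.0% at a fed input count of 1 and 0.66% at 2. By the fasted input it was 1.20% at 0, 0.42% at 1 and 0.21% at 2. Calls in the fed lists thus followed the fed input too, at lower counts than the test pooled. Whether this accounts for the few shared peaks cannot be told by this test. Dependence on the input was not particular to the bhb lists. In the fed H3K4me3 list 100% of bins with an input count of 2 or fewer and 0.070% of those with 6 or more lay in a peak. Yet 49.5% of fed H3K4me3 peaks overlapped a fasted peak. In the fasted H3K4me3 list the shares were 100% and 92.8%. Unequal depth alone was excluded, as at most 19.4% of fed bhb peaks overlapped a fasted peak. Wholly different H3K9bhb sites were excluded too, as 61.0% of the strongest bins were shared. For H4K8bhb, with 8.68% shared against at most 0.094% after shifting, different sites and other causes cannot be told apart.

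Genes of cholesterol synthesis had a smaller difference between diets than the median window in H3K9bhb, 0.30 log2 against 0.64, and not in H3K4bhb or H4K8bhb. Counting error was excluded, since the upper bounds of the differences between marks reached only -0.27. Dilution by background in H4K8bhb cannot be excluded. The list median there, 0.19, had a lower bound of 0.052 over genes, but the central 95% of random lists of like signal spanned -0.11 to 0.20. A list with no difference of its own could therefore give that value. An H3K9bhb antibody that also binds H3K9ac and a smaller gain of H3K9bhb at these promoters cannot be told apart. In windows of like H3K4me3 signal H3K9bhb correlated at 0.32 with H3K9ac and at 0.39 with H3K4me3, values too close to decide. H3K9ac and H3K4me3 correlated with each other at 0.65 there. Correlations of H3K9ac with the other bhb marks were 0.013 for H3K4bhb and 0.040 for H4K8bhb. Antibody tests on modified peptides would decide whether the H3K9bhb antibody also binds H3K9ac.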
